A study of Mus musculus with 10 samples.

How the data were processed

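Libraries of ribosome-bound RNA from dopaminergic neurons of the mouse ventral tegmental area, 5 control and 5 after restraint, were compared. The library kit was a Universal V10 RNA-seq kit, per the labels. Groups and replicate numbers came from the sample labels. The deposited table holds 1 column of whole-number read counts per library and gene. Counts were made with featureCounts 2.0.3 on exons grouped by gene with the GENCODE M30 annotation, per the file headers. The recorded options name paired-end input and neither a strand, counting of read pairs, nor multi-mapping reads, so each mate was counted, strands were not told apart, and reads that map to several places were left out, per the file headers. Reads were checked with FastQC, trimmed with Trimmomatic and aligned with STAR, per the submitters' processing notes, which give no versions. These notes name mm10 as the build, while GENCODE M30 is an annotation of GRCm39. Of 52071 genes matched by identifier and chromosome to GENCODE M21 (GRCm38, the same assembly as mm10), 93.9% had a start more than 10000 bases away, so coordinates are given as the table holds them, in GRCm39. Among counts of 1 to 30, 76.8 to 79.8% were even in the controls and 80 to 84.8% after restraint. Counting both mates gives mostly even counts. The groups did not overlap in this library measure, and the cause of that difference was not tested. Exon length per gene is the deposited value of the same table.

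The table lists 56691 genes, of which 52073 were given symbols by identifier from the GENCODE M21 gene names, and older symbols such as Mgea5 are used as that table gives them. No row lacked a gene identifier. Totals ran from 56082358 to 86584968 counts, and the median standard error of a log2 fold change was 0.136. Standard errors cover the spread between libraries. Genes were filtered with edgeR's filterByExpr (count minimum 10, total minimum 15), which left 18440, and normalized by TMM. Fold changes, standard errors and p-values came from edgeR 4.0.16 (glmQLFit and glmQLFTest, no robust option) with group as the only term, in R 4.3.3 with Python 3.11.15 for GC content and figures, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error was taken from the log2 fold change and the F statistic. Values per library are TMM-normalized CPM, and log2 CPM used a prior count of 2.

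Before the data were examined, the main test, the alternatives, 31 gene lists and the rule for named genes were fixed. The rule takes up to 10 genes per direction past the threshold, excluding predicted gene models, with at least 4 restraint libraries beyond the control median. Where fewer than 3 pass in a direction it adds the 5 with the smallest p in that direction, and it also takes 16 genes chosen in advance and up to 4 members with the smallest p of each list described. Some genes that the rule takes are not reported here. The lists cover activity, stress and STAT3 pathways, cell functions, and markers of the other cell types that the tissue could hold. 1 list held genes for checking the sex, and the other 30, with at least 5 measured members each, were tested with camera (limma 3.58.1) at a preset correlation of 0.01. They were tested again with an estimated correlation and with fry, and, after the data were seen, by exact permutation of the list score over all splits of the libraries into 5 and 5. The length slope of a library is the slope of its log2 CPM, relative to the mean of all libraries, on log2 exon length, over 8352 genes with a mean log2 CPM above 4 and outside the ribosomal protein, respiratory chain, immediate early and dopamine neuron lists.

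Of 86 named genes, 26 share exon bases with another annotated gene, and reads that overlap both were not assigned. The share was 39% for Ndufb6 and 24.4% for Spry1, whose overlapping genes held 88 and 164 counts in all. For Psmb7 it was 11.8%, with Nek6 on the opposite strand, for Nefm 19.2%, with Nefl, and for Cebpd 15%, with Spidr.

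Alternatives were other normalizations (RLE, upper quartile, library size only), filters (at least 1 count, or a CPM of at least 1 in 5 libraries), tests (DESeq2 1.42.0, limma-voom with and without quality weights, robust estimation), a block for the replicate number, 1 surrogate variable (sva 3.50.0), leaving out each library, and leaving out the genes of the mitochondrial genome. Halved counts and the removal of each library's length or GC trend (lowess, span 0.3) were added after the data were seen. GC content came from GENCODE M21 transcripts. The gene test was tested on simulated data with added 1.5-fold and 2-fold changes, on 18028 genes: it recovered 59% of 1.5-fold and 90% of 2-fold changes, and 5.7% of its 158 calls were unchanged genes. The changes were added only to genes above a minimum mean count, so these rates do not cover genes with few counts. The list test, tested on simulated data with a raised immediate early list, recovered a median of 0.37 and called 0 other lists. That median lay above the log2 rise that had been added. The simulated genes were drawn independently, without the correlation estimated between members of the real lists (up to 0.58, for ribosomal protein genes). The simulation therefore does not give the rate of false list calls in these data. Other splits of the real libraries into 5 and 5 called a median of 8 lists.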

Results

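The ventral tegmental area, a midbrain region that holds many of the brain's dopaminergic neurons, was taken from male C57BL/6 mice after 30 min of acute restraint or without restraint. RNA bound to ribosomes was enriched from dopaminergic neurons that carried a construct labelled NBL10-HA and was sequenced. Restraint is a short stressor in which the animal is kept from moving. There were 5 control libraries and 5 restraint libraries, with totals of 56082358 to 86584968 counts. No library of unenriched RNA was analysed here, so the degree of enrichment was not measured. Th, which encodes the rate-limiting enzyme of dopamine synthesis, had 411 ± 78.6 CPM in the controls (SD, n = 5). Gfap, an intermediate filament gene of astrocytes, had 1919 ± 121 CPM in the same libraries. Rpl10a, a ribosomal protein gene named here after its values were seen, held the most counts in each library (0.825 to 1.09%). Its log2 fold change was -0.00 ± 0.09 (SE). It had 9352 CPM in controls, against 572 CPM for Rpl3, another ribosomal protein gene. Whether transcripts of the NBL10-HA construct add to the counts of Rpl10a was not tested, so the level of the gene itself is uncertain. Counts of Xist, 0 to 26 per library, and of the Y-linked gene Ddx3y, 5503 to 9287, matched the stated sex. Restraint 1 stood apart from the other 9 libraries on the first principal component of log2 CPM, which held 22.6% of the variance. Its score was 92.1, against -19.2 to 4.1 for the others, and it had the fewest genes with a count (20936, against 22268 to 24513).

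The comparison addressed which signalling pathways change in RNA enriched from these neurons after restraint. The astrocyte gene Gfap stood above Th in controls, so RNA of other cells was present. The shifts below are therefore not assigned to a cell type. Immediate early genes, which neurons switch on within minutes of activity, were higher after restraint as a group, with a median log2 fold change of 0.36 over 38 measured members, 34 of them positive (camera with a preset correlation; adjusted p = 0.062 with an estimated correlation). Nuclear genes for ribosomal proteins and for the respiratory chain were lower as groups, with medians of -0.24 (72 of 86 negative) and -0.21 (72 of 80 negative) at the preset correlation (adjusted p = 0.342 with an estimated correlation for each). Genes that mark dopamine neurons were higher, with a median of 0.21 (22 of 28 positive; adjusted p = 0.342 with an estimated correlation), as were target genes of the transcription factor STAT3, with a median of 0.19 (19 of 24 positive; adjusted p = 0.101 with an estimated correlation). Stat3 itself, at 82.4 ± 2.06 CPM in controls and 83.6 ± 10.3 CPM after restraint (SD, n = 5 each), and Ogt, which encodes the enzyme that adds O-GlcNAc, showed no difference beyond the spread between libraries.

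Few single genes passed the test. Of 18440 genes tested, 1 was higher and 3 were lower after restraint at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 17 and 49 at an adjusted p under 0.1. DESeq2 passed 139 and 192 genes, and limma-voom 1 and 3. An unadjusted p under 0.05 was reached by 2154 genes, where 922 would be 5% of the tests. Rpl22l1, a paralogue of the ribosomal protein gene Rpl22 (chromosome 3, 28859585 to 28861573, GRCm39), fell from 29.1 ± 7.44 to 10.3 ± 4.35 CPM, or to 0.354 of the control level (SE of the log2 fold change 0.24). Control 5, at 16.4 CPM, lay apart from the other controls at 29.4 to 35.0 CPM. Psmb7, which encodes a beta subunit of the proteasome (chromosome 2, 38478048 to 38534099), fell from 98.4 ± 10.2 to 66.3 ± 5.70 CPM (log2 -0.57 ± 0.09). Polr1c, a subunit of RNA polymerases I and III (chromosome 17, 46554846 to 46558980), fell to 0.664 of its control mean of 31.2 CPM (log2 -0.59 ± 0.09). The gene that rose, Gm10736, lies outside the rule for named genes and was named after its value was seen. It is a 78-base processed pseudogene on chromosome 13 (111730068 to 111730145) and rose by 1.22 ± 0.19 on the log2 scale, from 34.2 ± 7.57 to 79.5 ± 27.1 CPM. Its source gene was not determined here, so the origin of its reads is uncertain. The edgeR adjusted p of these 4 genes was 0.0444, and in each case all 5 restraint libraries lay beyond the control median. All 4 calls ended with robust estimation of the dispersion (0 genes past the threshold, 2154 at an unadjusted p under 0.05), and when control 1, 2, 3 or 4 or restraint 3 or 4 was left out, and 1 of the 4 remained without restraint 1. Without restraint 5, by contrast, 9 genes passed as higher and 83 as lower, and without control 5, 4 and 16.

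Below these, 5 higher genes with the smallest p did not pass with edgeR. They were Nfkbia, which encodes an inhibitor of NF-kB (0.75 ± 0.13), Net1, a guanine nucleotide exchange factor for RhoA (0.63 ± 0.11), Nefh, the heavy neurofilament gene (0.58 ± 0.11), Scg3, a secretory granule gene (0.45 ± 0.09), and En1, a homeobox gene of midbrain dopamine neurons (0.57 ± 0.11). Their edgeR adjusted p ran from 0.0611 to 0.0662, and each was higher in 5 of 5 restraint libraries than the control median. All 5 passed with DESeq2, with adjusted p of at most 0.000529 (Scg3).

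The list tests gave 10 gene lists higher and 2 lower of 30 tested (camera with a preset inter-gene correlation of 0.01, Benjamini-Hochberg). With an estimated correlation 0 of the 30 held, with 4 at an unadjusted p under 0.05. With fry, which asks whether the members of one list move one way on balance, 3 held: immediate early genes (adjusted p = 0.0416), STAT3 target genes (0.0416) and MAPK negative feedback (0.0416). Over all genes tested, 1 member of the 30 lists (Rpl22l1, lower) passed with edgeR, 59 with DESeq2 (20 higher and 39 lower), 1 with limma-voom and 31 with limma-voom and quality weights (6 higher and 25 lower).

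The immediate early genes were higher in every restraint library than in any control, with list scores (mean log2 CPM of the members) of 3.86 ± 0.13 after restraint and 3.48 ± 0.17 in controls (SD, n = 5 each; exact two-sided permutation p = 0.00794, the smallest that 5 against 5 libraries can give, 0.238 after adjustment over the 30 lists). The list rose with camera (adjusted p = 7.26e-16; adjusted p = 0.062 with an estimated correlation). Adjusted over the list alone, 15 of 38 members rose (9 without control 4 or without restraint 5) and 0 fell; over all genes tested 0 passed with edgeR, 17 reached an unadjusted p under 0.05, and 8 rose with DESeq2. Fosb, a partner of Jun in the AP-1 complex, rose from 16.8 ± 3.32 to 28.4 ± 5.33 CPM (log2 0.76 ± 0.15), and Jun from 67.9 ± 6.27 to 89.6 ± 6.09 CPM (0.40 ± 0.08), both when adjusted over the list alone. By the same adjustment Egr4 rose by 1.34 ± 0.31, Zfp36, which encodes an mRNA-destabilizing protein, by 0.89 ± 0.21, the nuclear receptor gene Nr4a1 by 0.71 ± 0.17, Junb by 0.56 ± 0.17 and Fos by 0.54 ± 0.15. Arc (0.37 ± 0.15), Egr1 (0.35 ± 0.15), Dusp1 (0.25 ± 0.12) and Npas4 (0.28 ± 0.30) did not pass. Control 4 had the lowest list score, 3.19, against 3.50 to 3.60 in the other controls. Without it the list median was 0.29.

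**Figure D1:**
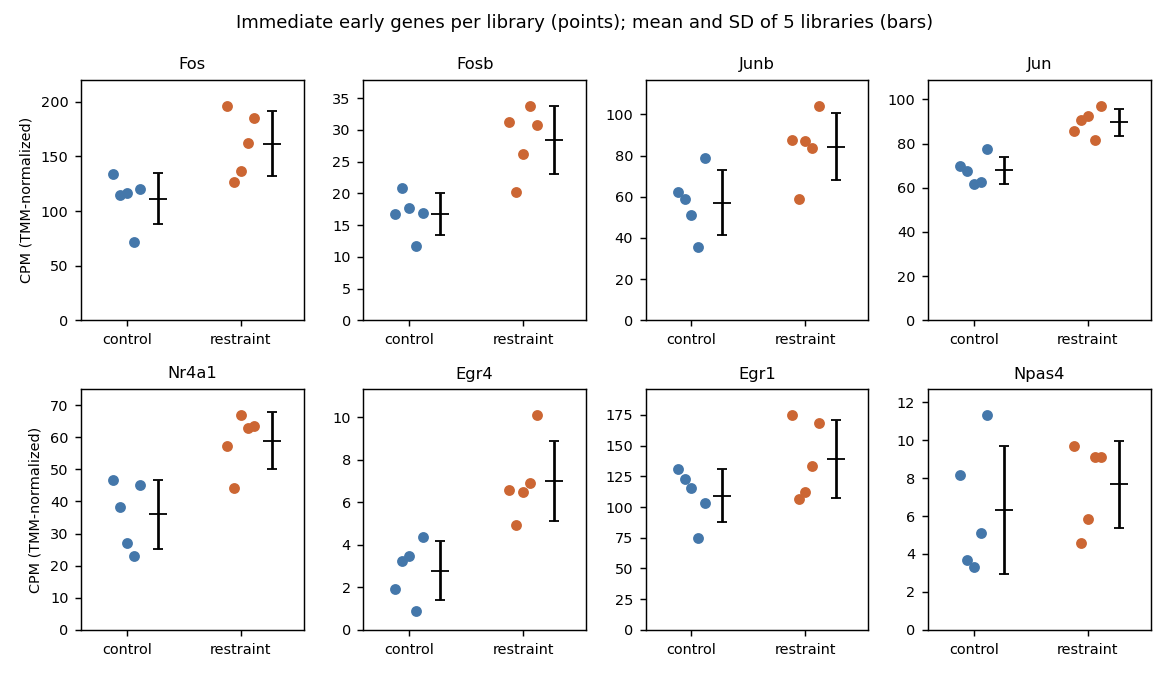
Each panel plots the TMM-normalized CPM of an immediate early gene in the 5 control and 5 restraint libraries (points), with the mean and SD of each group (bar) and the vertical axis starting at 0. Fosb had 16.8 ± 3.32 CPM in controls and 28.4 ± 5.33 CPM after restraint, while the groups of Npas4 (6.32 ± 3.39 and 7.67 ± 2.29 CPM) overlapped.

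STAT3 target genes rose as a list (camera adjusted p = 5.81e-07; adjusted p = 0.101 with an estimated correlation). Adjusted over the list alone 6 of 24 rose; over all genes 0 passed with edgeR, 7 reached an unadjusted p under 0.05, and 3 rose with DESeq2. The 6 were Gfap (0.37 ± 0.09), Cebpd (1.11 ± 0.27), Fos, Serpina3n, an acute-phase gene (0.42 ± 0.12), Junb and Osmr, the oncostatin M receptor gene (0.65 ± 0.20). Fos, Junb and Mcl1 also belong to the immediate early list and Gfap to the astrocyte markers. The 15 members found in no other list had a median of 0.15 (unadjusted camera p = 0.001, and 0.073 with an estimated correlation). Socs3, a feedback inhibitor that STAT3 induces, stood at 3.36 ± 0.69 CPM in controls and 4.00 ± 1.02 CPM after restraint (0.25 ± 0.20), which did not pass. Genes of NF-kB and cytokine signalling rose as a list (median 0.30, 12 of 14 positive, camera adjusted p = 0.000259; adjusted p = 0.126 with an estimated correlation). Of them Nfkbia and the adhesion molecule gene Vcam1 (0.35 ± 0.11) rose when adjusted over the list alone, 0 passed over all genes with edgeR (5 at an unadjusted p under 0.05), and 1 rose with DESeq2. Cxcl10 (0.40 ± 0.15) and Il1r1 (0.57 ± 0.23) did not pass.

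Glucocorticoid-responsive genes rose as a list (median 0.18, 16 of 23 positive, camera adjusted p = 0.00204; adjusted p = 0.494 with an estimated correlation). Nfkbia and Bcl6, a transcriptional repressor gene (0.40 ± 0.11), rose when adjusted over the list alone; over all genes 0 passed with edgeR (8 at an unadjusted p under 0.05) and 2 rose with DESeq2. Arrdc2 (0.50 ± 0.17), Klf9 (0.28 ± 0.10), the kinase gene Sgk1 (0.46 ± 0.22) and Fkbp5, which encodes a chaperone of the glucocorticoid receptor (-0.31 ± 0.13), did not pass. Genes of MAPK negative feedback rose as a list (median 0.06, 10 of 13 positive, camera adjusted p = 0.0407, and 0.259 with an estimated correlation). The exact permutation p of its list scores was 0.262 before adjustment. Its members Dusp1 and Dusp5 also belong to the immediate early list. Spred2 (0.32 ± 0.09) rose when adjusted over the list alone, 0 members passed over all genes with edgeR (2 at an unadjusted p under 0.05), and 1 rose with DESeq2, while Dusp14 (0.30 ± 0.11) and Spry1 (0.22 ± 0.13) did not pass. Integrated stress and unfolded protein response genes rose as a list (median 0.09, 14 of 20 positive, camera adjusted p = 0.00416; adjusted p = 0.342 with an estimated correlation). None of these passed alone with edgeR, over the list (0) or over all genes (0, with 6 at an unadjusted p under 0.05), or with DESeq2 (0). Its members with the smallest p were Ppp1r15a (0.33 ± 0.10), Calr (0.30 ± 0.11), Atf4 (0.28 ± 0.11) and Manf (0.27 ± 0.11). Heat shock genes rose as a list (median 0.08, 12 of 16 positive, camera adjusted p = 0.0212; adjusted p = 0.372 with an estimated correlation). Hsph1 (0.29 ± 0.08) rose when adjusted over the list alone, 0 members passed over all genes with edgeR (3 at an unadjusted p under 0.05) and 1 with DESeq2; Bag3 stood at 0.44 ± 0.16.

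**Figure D2:**
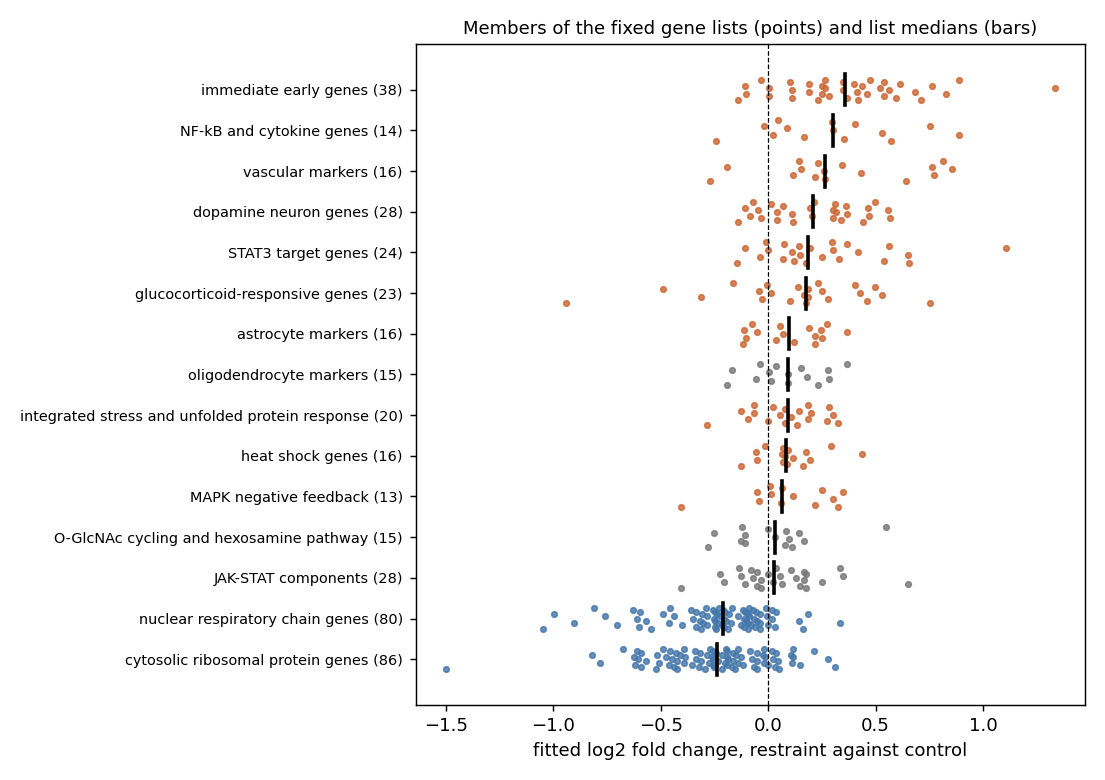
Points are the fitted log2 fold changes (horizontal axis, restraint against control) of the measured members of 15 gene lists, with their number in brackets, and black bars are list medians. Orange lists were higher and blue lists lower with camera at the preset correlation, and grey lists did not pass; medians run from -0.24 for the ribosomal protein genes to 0.36 for the immediate early genes.

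Cytosolic ribosomal protein genes fell as a list (camera adjusted p = 5.66e-24; adjusted p = 0.342 with an estimated correlation). Adjusted over the list alone 33 of 86 fell and 0 rose, over all genes 1 fell with edgeR (Rpl22l1), and 24 with DESeq2. Besides Rpl22l1, Rplp1 of the ribosomal stalk fell from 244 ± 32.8 to 138 ± 40.3 CPM (log2 -0.82 ± 0.16) when adjusted over the list alone. Of the 86 genes, 63 have pseudogenes named after them, 302 in all, and reads that map equally well to a gene and its copy were left out of the counts, so the levels of these genes are uncertain. Nuclear respiratory chain genes, which here include genes of the mitochondrial ATP synthase such as Atp5g3, fell as a list (camera adjusted p = 6.50e-19, and 0.342 with an estimated correlation). Adjusted over the list alone 19 of 80 fell (12 without control 3 and 31 without restraint 2) and 0 rose; over all genes 0 passed with edgeR, 29 reached an unadjusted p under 0.05, and 14 fell with DESeq2. Atp5g3 fell from 560 ± 88.3 to 299 ± 99.8 CPM (-0.90 ± 0.17), Ndufb6 by 0.76 ± 0.14, Atp5g1 by 0.57 ± 0.11 and Ndufv1 by 0.46 ± 0.08 on the log2 scale, each when adjusted over the list alone. Genes encoded in the mitochondrial genome did not pass (median 0.05, mean -0.01, 7 of 11 positive, camera adjusted p = 0.434). List scores of the ribosomal protein genes were 6.87 ± 0.12 in controls and 6.60 ± 0.22 after restraint (SD, n = 5 each; exact permutation p = 0.0476, 0.286 adjusted), and those of the respiratory chain genes 7.01 ± 0.13 and 6.74 ± 0.24 (exact permutation p = 0.0635, 0.298 adjusted). Libraries also differed in how log2 CPM changed with exon length. This slope ran from -0.0649 to 0.0688 log2 units per doubling of length in controls and from -0.0676 to 0.0891 after restraint. Over the 10 libraries it was correlated with the ribosomal protein score (Pearson r = -0.811, permutation p = 0.00429, adjusted 0.00858; Spearman rho = -0.673, permutation p = 0.0389, adjusted 0.0778) and with the respiratory chain score (r = -0.839, permutation p = 0.00265, adjusted 0.00858; rho = -0.794, permutation p = 0.00874, adjusted 0.035), among 4 lists so tested. Without restraint 4 and control 2, the libraries with the slopes farthest from the median, r was -0.733 and -0.843.

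**Figure D3:**
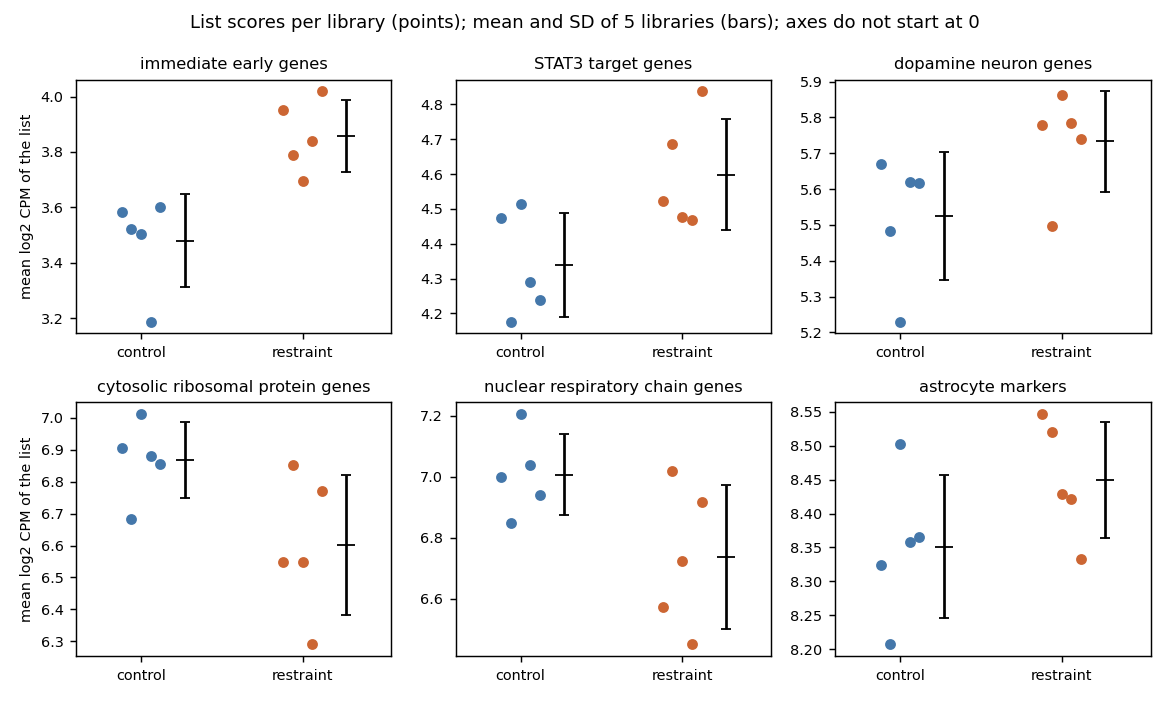
Each panel plots the mean log2 CPM of a gene list's members in the 5 control and 5 restraint libraries (points), with the mean and SD of each group (bar); the vertical axes do not start at 0. The immediate early scores of the groups did not overlap (3.48 ± 0.17 and 3.86 ± 0.13), while those of the ribosomal protein genes did (6.87 ± 0.12 and 6.60 ± 0.22).

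Dopamine neuron genes rose as a list (camera adjusted p = 1.83e-07; adjusted p = 0.342 with an estimated correlation). Adjusted over the list alone 4 of 28 rose; over all genes 0 passed with edgeR, 11 reached an unadjusted p under 0.05, and 3 rose with DESeq2. The 4 were the transcription factor genes En1, from 37.2 ± 5.91 to 55.1 ± 4.89 CPM, Foxa2 (0.46 ± 0.12) and Satb1 (0.31 ± 0.09), and the transporter-like gene Slc10a4 (0.50 ± 0.14). Th (0.21 ± 0.12), the dopamine transporter gene Slc6a3 (-0.03 ± 0.16) and the vesicular monoamine transporter gene Slc18a2 (0.19 ± 0.14) did not pass. Restraint 2 had the lowest Slc6a3 level of its group, 141 CPM against 223 to 267 CPM in the other restraint libraries, and without it the log2 fold change was 0.09. Ion channels of dopamine neurons (median 0.03, camera adjusted p = 0.118), ionotropic and GABA receptors (0.03, adjusted p = 0.492) and synaptic vesicle genes (0.06, adjusted p = 0.245) did not pass.

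Markers of other cell types did not move one way. Astrocyte markers rose as a list (median 0.10, 11 of 16 positive, camera adjusted p = 0.0212; adjusted p = 0.547 with an estimated correlation). Gfap, from 1919 ± 121 to 2471 ± 316 CPM, and Clu, from 1178 ± 123 to 1404 ± 47.9 CPM, rose when adjusted over the list alone; over all genes 0 passed with edgeR (4 at an unadjusted p under 0.05) and 1 with DESeq2. Agt (0.27 ± 0.12) and Ntsr2 (0.22 ± 0.10) did not pass. Vascular markers, most of them under 3 CPM in controls, rose as a list (median 0.26, 14 of 16 positive, camera adjusted p = 0.0266; adjusted p = 0.434 with an estimated correlation). No member passed with edgeR over the list alone (0) or over all genes (0, with 5 at an unadjusted p under 0.05), or with DESeq2 (0), and Flt1 (0.77 ± 0.28), Pecam1 (0.85 ± 0.31), Rgs5 (0.43 ± 0.18) and Itm2a (-0.27 ± 0.10) had the smallest p. Oligodendrocyte markers did not pass (median 0.09, camera adjusted p = 0.0715), with Ermn (0.37 ± 0.11) the 1 member that rose when adjusted over the list alone, and Mobp (0.28 ± 0.10), Trf (0.28 ± 0.13) and Mbp (0.15 ± 0.07) not passing. GABA neuron markers (median 0.07, adjusted p = 0.18) and glutamate neuron markers (0.01, adjusted p = 0.434) did not pass with camera. Pax5 (0.52 ± 0.15) rose when adjusted over the GABA list alone, and Pvalb (0.21 ± 0.14), Sst (0.23 ± 0.19) and Nefm (0.14 ± 0.10) did not pass. Slc17a7 (0.79 ± 0.48) was at 47.45 CPM in restraint 2 and 3.90 to 21.75 CPM in the other 9 libraries. Pou4f1 (0.42 ± 0.17), Neurod2 (0.53 ± 0.27) and Neurod6 (0.36 ± 0.22) did not pass. Without restraint 2 the log2 fold changes of Slc17a7 and Neurod2 were 0.05 and 0.12. Lower medians that did not pass were those of neighbouring region markers (-0.41, 7 of 8 negative, camera adjusted p = 0.14), ependymal and choroid plexus markers (-0.39, 6 of 8 negative, 0.136), serotonin and noradrenaline neuron markers (-0.32, 4 of 5 negative, 0.328) and blood cell genes (-0.17, mean 0.16, 4 of 7 negative, 0.544). Microglia (-0.01, mean 0.10, 7 of 14 negative, 0.505) and oligodendrocyte precursor markers (0.00, mean -0.08, 5 of 10 negative, 0.734) did not pass.

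Genes for components of the pathway named in the study's title did not move in a shared direction, unlike STAT3 target genes at the preset correlation. JAK-STAT components had a median of 0.03 (16 of 28 positive, camera adjusted p = 0.492; unadjusted p = 0.000215 with fry for shifts either way), and 0 of them passed with edgeR (over the list alone or over all genes, with 4 at an unadjusted p under 0.05) or DESeq2. Pias3, an inhibitor of STAT3 (-0.40 ± 0.12), Osmr (0.65 ± 0.20), Ptpn2 (0.33 ± 0.13) and Socs7 (-0.22 ± 0.09) had the smallest p. O-GlcNAc cycling and hexosamine pathway genes had a median of 0.03 (8 of 15 positive, camera adjusted p = 0.939; unadjusted p = 0.0034 with fry for shifts either way), and 0 passed with edgeR (2 at an unadjusted p under 0.05) or DESeq2. Ogt stood at 139 ± 12.3 and 143 ± 6.88 CPM (0.03 ± 0.08), and Mgea5, also called Oga, which encodes the enzyme that removes O-GlcNAc, at 220 ± 12.3 and 201 ± 8.36 CPM (-0.13 ± 0.07). Nagk (-0.28 ± 0.09), Gfpt2 (0.55 ± 0.18) and Uap1l1 (-0.25 ± 0.12) did not pass. MAPK and STAT3 serine kinases (median 0.01, camera adjusted p = 0.79), stress peptides and their receptors (-0.04, 0.939) and interferon-stimulated genes (0.02, 0.939) did not pass. The deposited counts measure RNA and hold no value for phosphorylation or O-GlcNAcylation of STAT3.

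Of the variance in log2 CPM, 12.9% lay between the groups (exact one-sided permutation p = 0.0714, 9 splits as large with the real one included, highest other split 14.5%). The median share over all splits was 10.9%, so most of the 12.9% is what an arbitrary split gives. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples and do not separate technical from biological spread.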

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

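Of 240 groups of 5 values tested (named genes, list scores and library totals), 14 had a library whose distance to its nearest neighbour exceeded 0.71 of the group's range. Chance flags about 1 in 20 groups. For the immediate early genes, the covariate tests and the tests without a library were set before their results were seen.

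Control 4 accounted for 4 of these. Its immediate early score of 3.19 lay below the other controls at 3.50 to 3.60 (gap 0.763 of the range), as did its log2 CPM of Fos, 6.16 against 6.84 to 7.06 (0.751). It was also low for Neurod6, 1.41 against 1.97 to 2.18 (0.734), and high for Gfpt2, 2.71 against 1.84 to 2.04 (0.77). For the higher immediate early genes, a single deviating library is argued against, since the list median nearest 0 over the 10 fits without a library was 0.286, without control 4. The median was 0.348 with each library's dopamine neuron score as a covariate and 0.352 with its astrocyte score, so a different share of dopamine neuron or astrocyte RNA may contribute but leaves the list past its threshold at the preset correlation (without these covariates, adjusted p = 0.062 with an estimated correlation). Of 100 splits of the 10 libraries into 5 and 5, the real one included, 1 gave a median as far from 0; the real value was 0.358 and the highest other 0.320. A response to restraint is the explanation that the design names and stays open as a hypothesis, as do differences in handling before the tissue was taken, which no table tests.

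Control 5 was low for Rpl22l1, log2 CPM 4.04 against 4.88 to 5.13 in the other controls (gap 0.771 of the range), for Pou4f1, 3.11 against 3.91 to 4.14 (0.775), and for the GABA neuron score, 5.87 against 6.12 to 6.19 (0.77). It was high for Pecam1, 0.64 against -0.54 to -0.32 (0.817).

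Restraint 5 was low for Agt, log2 CPM 7.58 against 8.10 to 8.21 (gap 0.826 of the range), and for Neurod6, 1.36 against 2.26 to 2.61 (0.715). Restraint 2 was low for Slc6a3, 7.14 against 7.80 to 8.06 (0.72). Among the controls, control 2 was low for Scg3, 8.07 against 8.35 to 8.46 (0.713), control 1 was high for Socs3, 2.21 against 1.57 to 1.69 (0.807), and control 3 was high for Cebpd, 4.11 against 3.10 to 3.23 (0.875).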

How the results depend on the processing

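Halved counts, the length and GC trends and the exact permutation of list scores were chosen after the data were seen. The number of genes past the threshold (1 higher, 3 lower) moved with library size only (5 and 12), no filter (103 and 199), DESeq2 (139 and 192), quality weights (21 and 66), robust estimation (0 and 0), 1 surrogate variable (106 and 238), the length trend removed (18 and 49) and an adjusted p under 0.1 (17 and 49); the cause was not tested. Without 1 library the counts ran from 0 to 9 higher and from 0 to 83 lower. The 4 genes called remained among the calls with library size only, no filter, DESeq2, quality weights, the surrogate variable and the length trend removed, and when control 5, restraint 2 or restraint 5 was left out, and 1 of the 4 remained without restraint 1. Replicate numbers showed no sign of pairing the libraries. Same-numbered deviations from the group means correlated at -0.164 to 0.027, and no control correlated best with its own number. The labels do not say whether the numbers mark shared days, so pairing is not excluded. With the replicate block 0 genes were higher and 0 lower, with 1704 at an unadjusted p under 0.05. Lists past the threshold numbered 12, and 10 to 16 over the other normalizations, filters, tests and left-out libraries, but 0 with an estimated correlation and 3 with fry. By exact permutation of list scores 0 passed (5 at an unadjusted p under 0.05), but with 5 against 5 libraries this test could hardly pass any of 30 lists: the immediate early scores, which did not overlap, had an adjusted p of 0.238. At the preset correlation the call of MAPK negative feedback ended in 6 of 25 alternatives (adjusted p up to 0.130), of vascular markers in 5 (0.122), of astrocyte markers in 4 (0.165), and of glucocorticoid-responsive (0.0824) and heat shock genes (0.0972) in 2 each; the cause was not tested. The immediate early median was 0.29 to 0.41 throughout; with an estimated correlation (0.36, adjusted p = 0.062) it was no longer past the threshold. The separation of the groups was 12.9%, and 13.2 to 15.4% without 1 library. These shares cannot be set against each other, since an arbitrary split takes up more of the variance when there are fewer libraries. The separation passed an exact permutation p under 0.05 without restraint 2 (14.9%, p = 0.0397), restraint 4 (14.4%, p = 0.0317) and restraint 5 (15.4%, p = 0.0317). Fold changes of named genes kept direction and side of the threshold in 1954 cases, passed it in 143 and lost it in 35. Those that changed sign lay near 0: Rpl10a with RLE and DESeq2 (0.0012), limma-voom (0.0112), the block (0.0105), the surrogate variable (0.0011) and the length trend removed (0.00957), and Stat3 with quality weights (-0.0185). Without 1 library Rpl10a ran from -0.0416 to 0.0606, Stat3 from -0.0503 to 0.0637, Slc6a3 from -0.13 to 0.0938 and Ogt from -0.00688 to 0.0644.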

Other observations

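The tests of length, of the length slope, of the dopamine sublists, of the list scores by exact permutation and of the unadjusted counts over splits were chosen after the values they concern had been seen; the others were set before.

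Ifi27, an interferon-stimulated gene, fell from 58.0 ± 9.48 to 37.8 ± 8.93 CPM (log2 -0.62 ± 0.15, edgeR adjusted p = 0.00958 over the list alone and 0.118 over all genes), while the list had a median of 0.02. Metallothionein Mt2 stood at -0.94 and Mt1 at 0.43, neither passing over the glucocorticoid list (adjusted p = 0.0971 and 0.112 with edgeR). Serotonin and noradrenaline neuron markers differed between libraries of the same group, with scores of 0.40 and 0.50 in restraint 3 and 4 and 2.20 to 3.12 in restraint 1, 2 and 5.

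Ribosomal protein and respiratory chain genes were lower together after restraint at the preset correlation. Both calls ended with an estimated correlation (adjusted p = 0.342 each), and the exact permutation p of the list scores was 0.0476 and 0.0635 before adjustment. Exon length as the whole cause is argued against. With each library's length trend removed the medians were -0.197 and -0.146. Random lists matched on length and expression centred at -0.0137 and -0.0199. All 10000 lay above the uncorrected medians. They were drawn gene by gene and lack the correlation within these lists, so that count carries little weight. With the length slope as a covariate the list medians were -0.194 and -0.157. Over the fits without a library the medians nearest 0 were -0.157 and -0.146, both without restraint 4. Length may account for part of the shift, since each correction brought the medians closer to 0. RNA integrity or a library step that acts on these transcripts beyond length stays open, as does a response to restraint, and no table decides between them.

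Dopamine neuron genes were higher after restraint at the preset correlation, with adjusted p = 0.342 with an estimated correlation and an exact permutation p of 0.0794 before adjustment. A purer pull-down could raise all of them alike. The 10 transcription factor genes of the list (median 0.31) and the 7 genes of dopamine synthesis and transport (median 0.04) differed in their shift (difference of scores 0.196, exact two-sided permutation p = 0.0238; p = 0.0635 without restraint 2, 3 or 4). These sublists were chosen after the values of their genes were seen, so the p weighs neither for nor against a purer pull-down, which stays open. A single deviating library as the whole cause is argued against, with medians nearest 0 of 0.134, without restraint 3, and 0.135, without control 3. With all libraries the median was 0.21, so either library may supply part of the shift. Among markers of other cells, which a purer pull-down would lower, vascular (median 0.26) and astrocyte markers (0.10) were higher at the preset correlation. With an estimated correlation neither held (camera adjusted p = 0.434 and 0.547). Positive medians that did not pass were those of oligodendrocytes (0.09), their precursors (0.00, with a mean of -0.08), GABA neurons (0.07) and glutamate neurons (0.01). Negative medians, none passing, were those of ependymal and choroid plexus cells (-0.39), neighbouring regions (-0.41), serotonin and noradrenaline neurons (-0.32), blood cells (-0.17) and microglia (-0.01). The means of blood cell genes (0.16) and microglia markers (0.10) were positive. These markers did not move one way.

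Over 100 splits of the 10 libraries, the real one included, 3 gave as many genes past the threshold as the real split (4), and the highest other split gave 78, by setting control 1, 3 and 4 with restraint 2 and 5 against the rest. A split with so many more calls points to a structure among the libraries. The length slopes of control 1, 3 and 4 and restraint 2 and 5 ran from -0.0676 to 0.00219. Those of the rest ran from -0.0271 to 0.0891. This split thus largely followed the length slope, but no test of that was run. An unadjusted p under 0.05 was reached by at least the real 2154 genes in 4 of the 100 splits, with 2927 the highest other and 608 the median. For the number of lists past the threshold at the preset correlation, 21 of the 100 splits gave at least the real 12, with 15 the highest other and 8 the median, so chance cannot be excluded for that count.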
